A study of Homo sapiens with 51 samples.

How the data were processed

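MicroRNA (miRNA) was measured by real-time PCR in tracheal aspirates, fluid suctioned from the windpipe, from 25 premature infants with bronchopulmonary dysplasia (BPD, a chronic lung disease of prematurity) and 26 control patients. Per the labels, the controls had neither lung disease nor prematurity, so a difference between the groups cannot be assigned to BPD or to prematurity. Per the labels' protocols, RNA was purified from 0.5 mL of aspirate, 200 ng was reverse transcribed, and 1066 human miRNAs were assayed on a SYBR Green PCR array. The instrument, the software and the authors' statistical test are not given in the sources used here. Each sample was taken as 1 donor, with its group from the labels. Among Ct values under 35, no 2 samples shared an exactly equal value for any miRNA, and the highest correlation of 2 samples was 0.931.

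The authors deposited raw cycle threshold values (Ct, the PCR cycle at which an assay's signal crosses a threshold, lower with more template) for 1066 miRNA and 5 small RNA control assays. Of the 54621 values, 25.3% were given as undetermined. All 5 control assays were given as 0 in 6 samples, which was read as no value. The authors also deposited fold changes, linear ratios per sample for 928 miRNAs made, per the series' design text, by global mean normalization and the 2-ΔΔCt method. The values show that the authors' normalizer was the mean Ct of all assays detected in the sample, to within 5e-10 cycles, and that the ratio was taken against 1 control sample for 793 of the miRNAs. The deposited ratios do not exceed 25, and 757 values sit at that bound. Before log2 was taken, ratios under 0.001 were set to 0.001; of 9605 values at or under it, 9598 belong to undetermined assays. The 6 other columns of the deposited tables were empty and were not used.

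The order of the rows was checked by correlating each sample's Ct values, in 3 parts of the list, with the median of the other samples at shifts of up to 30 rows. In 41 samples the listed order gave the highest correlation in every part. In 9 samples the values from row 373 on were displaced by 12 rows and those from row 757 on by 24 rows, which affects 65.1% of their miRNA values. In 1 further control sample the values from about row 871 on were displaced by 2 rows. The comparisons use the values as deposited for all samples, as fixed before the data were examined. The tests of miRNAs, lists, list contrasts, raw Ct, detection frequency and spread were repeated without the 9 samples and with the rows moved back. Moving rows back leaves 24 rows of the 9 samples without a value. The authors' fold changes derive from the same listed values. Samples were also split into 3 technical batches: the 9 displaced samples (4 BPD, 5 control), the 6 with control assays at 0 (2 BPD, 4 control) and the remaining 36 (19 BPD, 17 control). The technical batch was used as a block, and each batch was also fitted alone for the test of miRNAs and compared alone for the lists that passed. The batches of 6 and 9 are small, with 2 and 4 BPD samples; in the batch of 6 an exact test has 15 splits and cannot give a p under 0.05.

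A miRNA was called detected at a Ct under 35, and undetermined values were set to 35. Relative level is minus delta Ct, the sample's mean Ct over the 106 miRNAs detected in every sample minus the miRNA's Ct. It is on the log2 scale, so 1 unit is a 2-fold difference if each cycle doubles the product. The test covered 939 miRNAs detected in at least 50% of the samples of a group. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per sample were compared by two-sided permutation tests with 100000 resamples. Detection was compared by Fisher's exact test per miRNA. The spread of the groups was compared by permuting labels on residuals, with 10000 resamples. The 20 miRNA lists (cell types, families, clusters and lung-injury literature) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested. The array uses older names, in which an asterisk marks the minor arm and the plain name the dominant one. Members were matched by exact name and otherwise through a table of dominant arms, which refines the matching rule fixed beforehand. Assays that name several miRNAs (8 of them) cannot tell these apart.

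The rule for named miRNAs took the 12 largest increases and 12 largest decreases past the threshold among miRNAs detected in at least 80% of the higher group, or, if fewer than 10 passed, the 10 with the smallest p, plus list members and control assays. The fits were tested on simulated data, in which 200 miRNAs were moved by known amounts under shuffled labels. With the deposited values of all samples (936 miRNAs in that fit), 12% of 2-fold, 60% of 4-fold, 86% of 8-fold and 74% of 16-fold changes were recovered, 50 of each having been made, with 0 calls among 738 unmoved miRNAs. With realigned rows (907 miRNAs), 26%, 58%, 90% and 96% were recovered. Moving 200 miRNAs at once makes the adjusted threshold easier to reach, so these shares do not give the power for few changed miRNAs. With the deposited values the median estimate was 1, 0.822, 0.829 and 0.603 of the true log2 change at 2-, 4-, 8- and 16-fold. In a simulation on 931 miRNAs, camera called 10 of 10 lists of 8 random miRNAs moved by 1 on the log2 scale and 0 of 10 unmoved lists; random lists lack the correlation of a real family. Alternatives covered the normalizer, the Ct limit, undetected values, the filter, the test, covariates, the row order and the samples used. No spike-in assay is among the deposited rows, so that planned normalizer was not run. The deposited tables give no plate, so the planned normalizer per plate was run only with each part of the list taken as a plate, as an alternative added after the data were seen. Figures were drawn with matplotlib 3.10.9.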

Results

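The miRNA content of tracheal aspirates was compared between 25 premature infants with BPD and 26 controls without lung disease or prematurity. Between 371 and 1038 of the 1066 miRNAs were detected per sample, with a median of 807. The mean raw Ct over the 106 miRNAs detected in every sample ran from 25.0 to 31.1 cycles. At the detection limit of 35 cycles, 556 miRNAs were detected in at least 80% of samples.

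In 9 samples, 4 BPD and 5 control, the listed rows did not follow the profile of the other samples beyond the first 372 miRNAs. Over those first rows their median correlation with the median of the 41 samples in listed order was 0.852. It was -0.013 over the middle part of the list and -0.084 over the last part. After the rows were moved back by 12 and 24 places the medians were 0.897 and 0.881. Values for miRNAs of the middle and last parts therefore include other assays' Ct in these samples. The 106 normalizing miRNAs come from the whole list, so the normalizer and the mean raw Ct of these samples are affected too. Through the normalizer the levels of first-part miRNAs also shift. The mean difference of the let-7 family, for example, was -0.59 as deposited and -0.50 with realigned rows. Values without these samples or with realigned rows are given below for the counts, the lists that passed and the list contrasts.

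**Figure D1:**
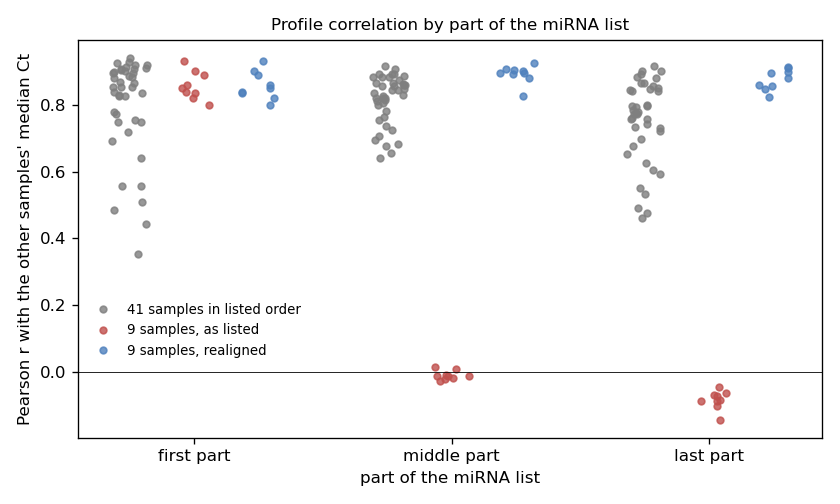
Pearson correlation of each sample's Ct values with the median of the other samples (vertical axis) in the first, middle and last part of the miRNA list (horizontal axis). For the 9 displaced samples the median is that of the 41 samples in listed order. Each point is 1 sample: 41 samples in listed order (grey), and 9 samples as listed (red) and after realignment (blue); 1 partly displaced sample is not drawn. The 9 samples lie near 0 as listed in the middle and last parts, with medians of -0.013 and -0.084, and at medians of 0.897 and 0.881 after realignment.

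Among the assays of the first 372 rows, which the displacement does not touch, the lowest Ct values belonged to miR-21, a miRNA of many epithelial and immune cells, and miR-223, a miRNA of neutrophils and other myeloid cells. miR-21 had a Ct of 23.4 ± 2.99 in BPD (SD, n = 25) and 22.9 ± 1.94 in controls (SD, n = 26). For miR-223 the Ct was 24.0 ± 3.38 in BPD and 24.7 ± 2.73 in controls. Next came miR-26a at 25.6 ± 2.26 in BPD and 24.8 ± 2.76 in controls, and the epithelial miR-200c at 25.9 ± 2.30 in BPD and 24.9 ± 2.67 in controls. let-7b had a Ct of 27.2 ± 2.17 in BPD and 25.9 ± 1.66 in controls. Over the whole list with realigned rows, the assay named miR-1280 had the lowest Ct, at 21.4 ± 2.32 in BPD and 20.3 ± 2.22 in controls. It was followed by the assays named miR-1260 and miR-720 and then by miR-21. These are raw values of separate assays, and their order also depends on each assay's efficiency. Which RNA the miR-1280, miR-1260 and miR-720 assays amplify was not tested.

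The main comparison asked which miRNAs differ in level between BPD and control aspirates. In limma, 0 of 939 miRNAs passed an adjusted p of 0.05, and therefore 0 were called higher and 0 lower in BPD. At an unadjusted p under 0.05 there were 20, 10 higher and 10 lower, where 47 would be expected by chance alone. Such counts vary widely, so 20 is not a marked deficit. In random splits of the samples the median count was 26 and the highest 317, and 65 of 100 splits, the real one included, reached 20. With realigned rows, where the count was 31, the median was 35 and 57 of 100 splits reached 31. A permutation test per miRNA also called 0, with 21 at an unadjusted p under 0.05, and a t-test on the linear scale called 0, with 18. The count was 0 without the 9 displaced samples, with 29 of 874 at an unadjusted p under 0.05, and 0 with realigned rows, with 31 of 915. With the technical batch as a block it was 0 with 49 of 939, and in the batch of 36 samples 0 with 52 of 885, where 47 and 44.2 would be expected. Within the batch of 6 samples it was 0 with 27 of 1017, and within the batch of 9, realigned, 0 with 46 of 964. Some samples in listed order followed the others weakly even over the first rows, with a correlation down to 0.353. With realigned rows and without the samples under 0.6 there, 0 of 893 passed, with 22 at an unadjusted p under 0.05. The lists were not tested without these samples. The standard error of a log2 difference had a median of 0.49, and the 95% interval of 88.1% of the miRNAs lay within 4-fold in either direction (log2 of -2 to 2). These intervals hold for levels as computed, with undetermined values set to a Ct of 35 and displaced rows included. In the simulation with deposited values the median estimate was 1 of the true log2 change at 2-fold, 0.822 at 4-fold, 0.829 at 8-fold and 0.603 at 16-fold. Larger true differences are therefore not excluded by the intervals, and smaller differences are not excluded by these data either.

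Since no miRNA passed, the 10 with the smallest p are named here. The level of miR-3131 was 0.40 ± 2.07 in BPD and -0.99 ± 1.35 in controls, a log2 difference of 1.39 (SE 0.49, p = 0.00647, limma adjusted p = 1). miR-146a, an inflammation-induced miRNA that restrains NF-kappaB signalling, had a level of -0.87 ± 1.81 in BPD and -2.21 ± 1.86 in controls, a log2 difference of 1.34 (SE 0.51). The difference was 1.11 for miR-183* and 0.95 for miR-877*. miR-100 had a level of -1.91 ± 1.86 in BPD and -0.50 ± 1.87 in controls, a log2 difference of -1.41 (SE 0.52), which was -0.69 in the batch of 36 samples (unadjusted p = 0.283). miR-375, a miRNA of secretory epithelial and endocrine cells, had a level of -0.66 ± 1.95 in BPD and 0.57 ± 1.58 in controls, a log2 difference of -1.23 (SE 0.50). The other 4 differences were -1.15 for miR-145*, -1.03 for miR-505*, -1.19 for miR-514b-5p and -1.01 for miR-320a. Of these 10 assays, 6 lie in the displaced parts of the list. All 10 had the same sign with realigned rows, where 6 kept an unadjusted p under 0.05 and miR-145* was at -0.73 (unadjusted p = 0.124). As the 10 were picked for a small p in the same samples, the shared sign is no independent support. In the batch of 9 alone, realigned, the sign turned for miR-146a (-0.055), miR-145* (1.66), miR-505* (1.14) and miR-514b-5p (0.080). With realigned rows the smallest p belonged to miR-1287, named after its value was seen, with a log2 difference of 2.05 (SE 0.56, limma adjusted p = 0.526).

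Of 17 lists with at least 3 tested members, 2 passed an adjusted p of 0.05 with camera's preset correlation. The myeloid and pan-leukocyte list, miR-223, miR-223*, miR-142-3p and miR-142-5p, was higher in BPD, with a list mean of 0.37 ± 2.15 in BPD and -0.58 ± 2.44 in controls (camera adjusted p = 0.0109, and adjusted p = 0.463 with an estimated correlation). All 4 members had a positive difference: 1.22 for miR-223*, 1.09 for miR-223, 1.03 for miR-142-5p and 0.43 for miR-142-3p. The let-7/miR-98 family, miRNAs that accumulate as cells differentiate, was lower in BPD, with a list mean of 0.01 ± 1.67 in BPD and 0.60 ± 1.24 in controls (camera adjusted p = 0.00174, and adjusted p = 0.463 with an estimated correlation). All 9 members had a negative difference, from -0.93 for let-7b and -0.92 for let-7c to -0.078 for let-7f and -0.051 for let-7i. The last 2 were positive with realigned rows (0.013 and 0.040) and without the 9 displaced samples (0.20 and 0.035). Permuting the labels on the list mean gave p = 0.148 for the myeloid list and p = 0.158 for the let-7 family. Of their members, 0 passed adjusted over the list alone and 0 over all miRNAs tested. With realigned rows miR-223* was at 1.77 and passed adjusted over the list alone. Without the 9 displaced samples neither list passed (adjusted p = 0.0987 and 0.369), with mean differences of 1.09 for the myeloid list and -0.39 for let-7. With realigned rows both passed (adjusted p = 0.00982 and 0.00714), and the multiciliated epithelial list passed too, with a mean difference of -0.62 (adjusted p = 0.00344). With an estimated correlation 0 of these 3 calls held on realigned rows, with an adjusted p of 0.356 for the myeloid list, 0.512 for let-7 and 0.356 for the multiciliated list. All 9 let-7 assays and 3 of the 4 myeloid assays lie in the first part of the list, which is not displaced. Over that part alone, with the normalizer also taken from it, let-7 passed with a mean difference of -0.52 (adjusted p = 6.13e-05), and the 3 myeloid members did not pass, with a mean difference of 0.92 (adjusted p = 0.135). Within batches, with realigned rows, the myeloid difference was 1.23 in the batch of 36 (permutation p = 0.13), -1.14 in the batch of 6 (exact permutation p = 0.8) and 1.32 in the batch of 9 (exact permutation p = 0.302). For let-7 it was -0.28 (permutation p = 0.608), -1.43 (exact permutation p = 0.267) and -1.39 (exact permutation p = 0.206).

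**Figure D2:**
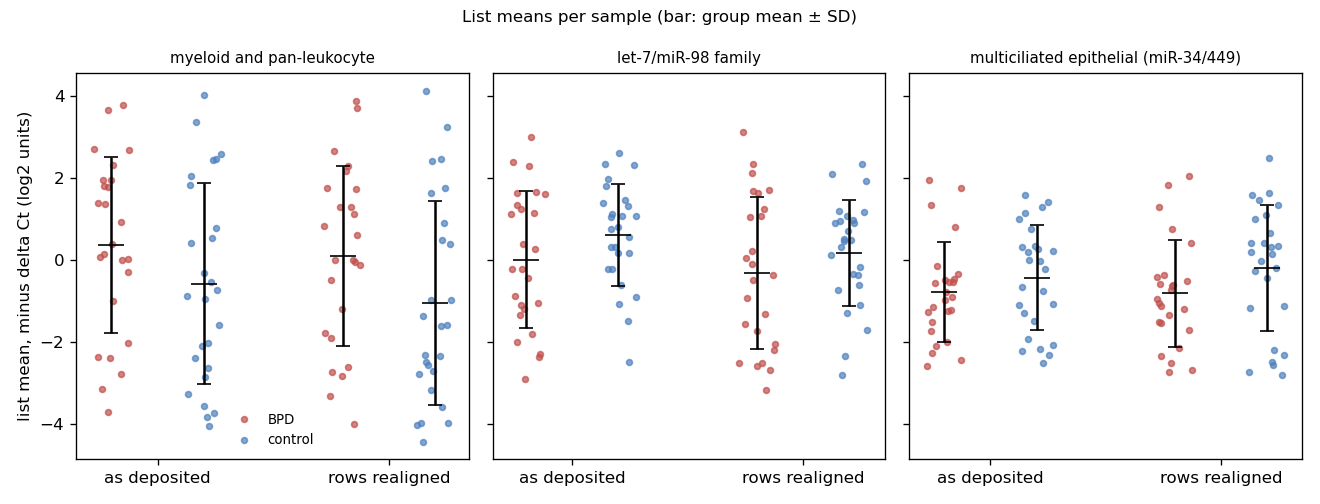
Mean level of 3 miRNA lists per sample, as minus delta Ct in log2 units (vertical axis), in BPD (red, n = 25) and control samples (blue, n = 26), from the values as deposited and with rows realigned (horizontal axis). Points are samples, and the black marks give the group mean with 1 SD; the groups overlap over most of their range, with myeloid means of 0.37 ± 2.15 in BPD and -0.58 ± 2.44 in controls as deposited.

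The other 15 lists tested with camera did not pass. For epithelial cells, the mean difference was -0.24 over 9 members of the miR-200 family (adjusted p = 0.466), -0.49 over 3 basal and squamous members (adjusted p = 0.215) and -0.34 over 8 members of the multiciliated miR-34 and miR-449 list (adjusted p = 0.215). Of those 8, only 2, miR-34c-5p and miR-449a, lie in the undisplaced first part of the list. With realigned rows the multiciliated list passed at -0.62, as given above, though not with an estimated correlation. The basal and squamous mean was -0.12 in the batch of 36. For blood cells, it was -0.52 over 6 erythrocyte members (adjusted p = 0.215), with miR-451 at -1.49 (SE 0.94), and -0.08 over 6 lymphocyte members (adjusted p = 0.821). The inflammation-induced list had a mean difference of 0.23 over 10 members (adjusted p = 0.215), with miR-21 at -0.15 and miR-155 at 0.17. The mesenchymal and smooth muscle list had a mean of -0.05 and a median of 0.05 over 9 members (adjusted p = 0.877). Among families, the mean was -0.23 for miR-17, miR-92 and their paralogous clusters (adjusted p = 0.219), -0.45 for the miR-29 family (adjusted p = 0.215) and -0.36 for the miR-30 family (adjusted p = 0.219). A list of miRNAs from the BPD and lung-injury literature had a mean of -0.22 over 10 members (adjusted p = 0.542). Of the lists not expected of airway, the muscle list had a mean of 0.08 (adjusted p = 0.705), the embryonic stem list 0.18 (adjusted p = 0.215), the placental chromosome 19 cluster 0.01 (adjusted p = 0.705) and the imprinted 14q32 cluster -0.04, with a median of 0.06 (adjusted p = 0.536). In these 15 lists 0 members passed over all miRNAs tested and 0 adjusted over the list alone. Among alternatives, 1 member of the inflammation-induced list passed adjusted over the list alone in the first part. In the batch of 36, 1 member of the mesenchymal list did so. With realigned rows 14 of them did not pass either, with adjusted p from 0.129 to 0.767, and without the 9 samples 0 of the 15 passed, with adjusted p from 0.614 to 0.982. The lists with under 3 tested members had mean differences of -0.46 (endothelial miR-126 and miR-126*), -0.65 (miR-210, induced by hypoxia) and 0.03 (liver and neuron). In the last, the 2 members tested were miR-124 and miR-129-5p, and the liver miR-122 was not tested. The endothelial mean was -0.85 in the batch of 36 and -0.71 without the 9 samples.

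Lists were also set against each other within each sample, which needs no normalizer. The myeloid list exceeded the miR-200 family by 1.33 ± 2.10 in BPD and 0.15 ± 2.51 in controls, a difference of 1.19 with a 95% interval of -0.12 to 2.49 (permutation p = 0.0721, adjusted p = 0.216 over 3 contrasts). With realigned rows the difference was 1.50, with an interval of 0.15 to 2.85 (permutation p = 0.0303, adjusted p = 0.091), and without the 9 samples it was 1.11 (permutation p = 0.136). Within batches, realigned, it was 1.17 in the batch of 36 (permutation p = 0.119), -0.74 in the batch of 6 (exact permutation p = 0.933) and 3.12 in the batch of 9 (exact permutation p = 0.103). For the erythrocyte list against the miR-200 family the difference was -0.25, with an interval of -1.19 to 0.69 (permutation p = 0.598, adjusted p = 0.669). It was -0.023 with realigned rows (permutation p = 0.959) and -0.42 without the 9 samples (permutation p = 0.396). For the miR-34 and miR-449 list it was -0.10, with an interval of -0.58 to 0.38 (permutation p = 0.669). It was -0.27 with realigned rows (permutation p = 0.207) and -0.26 without the 9 samples (permutation p = 0.292).

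BPD samples had 773.1 ± 164.8 detected miRNAs and controls 815.7 ± 159.5 (permutation p = 0.354). The difference of -42.6 was -76.6 in the batch of 36 (permutation p = 0.154) and -0.10 with mean raw Ct as a covariate (permutation p = 0.997). The mean raw Ct was 28.6 ± 1.04 cycles in BPD and 28.2 ± 1.29 in controls (permutation p = 0.236). In the batch of 36 samples the difference in raw Ct was 0.77 cycles (permutation p = 0.0729), and with realigned rows it was 0.49 cycles (permutation p = 0.188). Fisher's exact test of detection frequency called 0 of 960 miRNAs, with 21 at an unadjusted p under 0.05. The median SD per miRNA was 1.70 in BPD and 1.78 in controls, a ratio of 0.956 (permutation p = 0.433).

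Among the control assays, SNORD61 had a raw Ct of 30.0 ± 2.74 in 23 BPD samples and 28.1 ± 2.77 in 22 controls, a difference of 1.87 cycles (permutation p = 0.0289, adjusted p = 0.144). SNORD68, SNORD95, SNORD96A and RNU6-2 differed by 1.07, 0.30, 0.60 and 0.34 cycles, with adjusted p from 0.415 to 0.77. In the batch of 36 samples SNORD61 differed by 2.13 cycles (permutation p = 0.012, adjusted p = 0.06), and the other 4 by 1.58, 0.52, 0.99 and 0.84 cycles, with adjusted p from 0.161 to 0.57. RNU6-2 was undetermined in 9 samples, 2 of them in the batch of 36. The values over 23 BPD samples and 22 controls include the displaced samples, whose control rows are open to doubt for reasons given below. The authors' deposited fold changes, tested on the log2 scale with limma, gave 0 calls among 902 miRNAs, with 31 at an unadjusted p under 0.05. Their direction matched that of the Ct values for 732 of the 902, and the differences correlated at r = 0.704 across miRNAs, which are not independent replicates.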

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

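No value met the rules for a closer look at single samples or at differences between contrasts, since both groups are larger than those rules cover and there is 1 contrast. The tests below were chosen after the results were seen, except the count of random splits for the lists, which was set beforehand.

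In 9 samples the later rows were out of step with the other samples. A different miRNA profile of these samples is argued against by the first 372 rows, where their median correlation with the 41 samples in listed order was 0.852. The control wells of each plate may have been left in the listing: the 2 sets of 12 rows at the points of displacement correlated at a median of 0.998 within a sample, against 0.086 for the same rows of 41 other samples. The last 2 rows of each set had Ct values of 17.4 to 19.2 in all 9 samples. Of 38 deposited control values in these samples, 1 equalled a value of those sets within 1e-06 cycles, so their control rows are open to the same doubt.

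No miRNA passed the threshold between BPD and control. That displaced rows hid large changes in many miRNAs at once is argued against by the realigned values. Their smallest adjusted p was 0.526, in a fit that recovered 90% of simulated 8-fold and 96% of 16-fold changes. The same fit recovered 58% of 4-fold and 26% of 2-fold changes. These changes were made in many miRNAs at once, which makes the adjusted threshold easier to reach. For changes in few miRNAs, or for smaller ones, the realigned values therefore cannot tell whether displaced rows hid them. Random splits say nothing about chance for a count of 0, which every split reaches (100 of 100), with a highest other count of 77 as deposited, 9 with realigned rows, and 1 each for the deposited fold changes and the detection frequency. The split with 77 calls points to a structure among the samples, and the displaced rows may be part of it, since the highest count of the same splits was 9 with realigned rows. Its nature, and smaller group differences, stay open.

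The myeloid list was higher and the let-7 family lower in BPD with a preset correlation, and neither passed with an estimated one (adjusted p = 0.463 for both). Members within a list were correlated, at an estimated 0.586 for the myeloid list and 0.647 for let-7. This correlation may account for both calls, as neither held once it was allowed for. The mean differences of 0.94 and -0.59 are the same in both tests by construction and do not bear on this. Chance cannot be excluded, as 51 of 100 splits put at least 2 lists past the threshold, the highest other split 11. Displaced rows as the whole reason are argued against for let-7 by its mean difference. Its 9 assays all lie in the undisplaced first part of the list, where that difference was -0.52 (adjusted p = 6.13e-05 with the preset correlation). The smaller adjusted p there does not make the let-7 difference firmer. Camera sets a list against the other miRNAs, and the median difference of all miRNAs was 0.14 there and -0.03 in the main fit. An estimated correlation was not run over that part. For the myeloid list, the mean difference argues against it too. That difference was 1.15 with realigned rows (adjusted p = 0.00982) and 0.92 over its 3 undisplaced members (adjusted p = 0.135), both with the preset correlation. With realigned rows and an estimated correlation neither list passed (adjusted p = 0.512 for let-7 and 0.356 for the myeloid list). A part played by the 9 samples stays open, as without them the adjusted p was 0.0987 for the myeloid list (mean difference 1.09) and 0.369 for let-7 (-0.39). More myeloid RNA in BPD aspirates stays open as a hypothesis, since the contrast with the miR-200 family within samples gave p = 0.0721, and prematurity cannot be separated from BPD.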

How the results depend on the processing

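Settings that realign rows, leave out displaced samples, take a single batch, use the first part of the list, take each part as a plate or block the lists on technical batch were added after the data were seen. The setting without samples of low correlation over the first rows was added then too. The count of miRNAs past the threshold, and of those higher in BPD, was 0 in all 31 alternatives, with a smallest adjusted p from 0.407 to 1 and 3 to 52 miRNAs at an unadjusted p under 0.05. Without normalization the median difference of all miRNAs was -0.42, and with the small RNA controls 0.22. The 10 named miRNAs kept their direction in 289 values computed and turned in 4, all in the batch of 9 alone with realigned rows. These were -0.055 for miR-146a, 1.66 for miR-145*, 1.14 for miR-505* and 0.080 for miR-514b-5p, and the cause was not tested. The 10 were picked for a small p in the same samples that most alternatives reuse. Their kept direction is therefore no independent support. No alternative moved the comparisons of detected miRNAs, raw Ct, detection frequency, control assays or deposited fold changes across the threshold. The median standard error of a log2 difference was 0.49, and 25.3% of the Ct values were undetermined.

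The number of lists past the threshold, 2 in the main setting, was 1 with small RNA controls, a Ct limit of 32, the filter for detection in every sample, undetected values left missing, the technical batch as a block or the first part of the list alone, and 0 without the 9 samples, in the batch of 36, with an estimated correlation or by permutation. The filter leaves 6 lists and the first part 15; for the other settings the cause was not tested, except the estimated correlation, which by construction widens the null. The myeloid list turned to -1.14, and its contrast with the miR-200 family to -0.74, in the batch of 6 alone (2 BPD, 4 control), where no exact test can pass. With its direction kept, the myeloid list lost its call at a mean of 0.81 with the limit of 32, 1.09 without the 9 samples, 1.23 in the batch of 36, 0.85 with the batch block, 0.92 in the first part, 0.75 with missing values, and 0.94 with an estimated correlation or by permutation. The let-7 family lost its call at -0.25 with small RNA controls, -0.39 without the 9 samples, -0.29 in the batch of 36, and -0.59 with an estimated correlation or by permutation. The setting with small RNA controls also leaves out the 6 samples without control values and uses the doubtful control rows of the 9 displaced samples. In the batch of 9 realigned (myeloid 1.32, let-7 -1.39) and the batch of 6 (let-7 -1.43) the lists were compared by exact permutation and not by camera. Those values do not tell whether the call would hold there. With realigned rows the multiciliated list passed at -0.62 (adjusted p = 0.356 with an estimated correlation, where the myeloid and let-7 lists did not pass either), and the myeloid contrast with the miR-200 family at 1.50 before adjustment.

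The other directions that turned belong to values past no threshold, and the cause was not tested. With small RNA controls the means were 0.17 (lymphocyte), 0.055 (miR-200 family), 0.21 (mesenchymal), 0.068 (miR-17 and miR-92 clusters), 0.056 (miR-30), 0.17 (lung-injury literature) and 0.16 (14q32). In the batch of 36 they were 0.096 (lymphocyte), 0.058 (miR-200 family), 0.054 (mesenchymal), 0.0020 (miR-29), 0.17 (miR-30), 0.027 (literature), -0.0053 (muscle) and -0.084 (chromosome 19). Without the 9 samples they were 0.079 (lymphocyte), 0.0099 (mesenchymal), -0.060 (chromosome 19) and 0.0090 (14q32), and with realigned rows 0.12 (lymphocyte), 0.15 (mesenchymal) and 0.10 (14q32). In the first part they were 0.059 (lymphocyte), 0.21 (mesenchymal) and 0.26 (14q32). With the limit of 32 they were 0.31 (mesenchymal) and 0.032 (14q32), with missing values 0.016 (14q32), with raw Ct as a covariate -0.034 (muscle) and -0.074 (chromosome 19), and with the mean of detected miRNAs -0.046 (chromosome 19). The erythrocyte contrast was 0.25 with missing values and 0.0022 with the limit of 32. The miR-34 and miR-449 contrast was 0.074 with missing values and 0.044 with medians. The ratio of spreads was 1.01 over miRNAs detected in every sample.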

Other observations

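Muscle miRNAs were near the detection limit in both groups. miR-206 was detected in 13 of 25 BPD and 15 of 26 control samples, and miR-133b in 15 and 16. miR-133a was detected in 39 samples of both groups together, at a mean Ct of 32.9. Some other miRNAs not expected of airway were found more widely: miR-124 in 50 samples (mean Ct 30.6), miR-129-5p in 49 (30.4) and the placental miR-515-3p in 48 (31.8). The liver miR-122 was detected in 18. Whether these assays are specific was not tested. miR-144, an erythrocyte miRNA, was detected in 10 BPD and 18 control samples, with a log2 difference of -1.09 (SE 0.75) that did not pass the test. miR-489, from the lung-injury literature list, was detected in every sample, at a level of 0.97 ± 1.35 in BPD and 0.25 ± 1.49 in controls, a log2 difference of 0.72 (SE 0.42, unadjusted p = 0.0952 in limma).

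Across 99 random splits of the samples, 69 put at least 1 list past the threshold with camera's preset correlation, with a median of 2 lists per split.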
